A study of Mus musculus with 10 samples.

How the data were processed

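The series measured RNA from the ileum, the last part of the small intestine, of 10 mice infected by gavage with 100 cysts of the ME49 strain of Toxoplasma gondii in 0.3 ml. Tissue was taken on day 5. Of the 10 arrays, 5 came from wild-type C57BL/6 mice (WT) and 5 from mice lacking interleukin-22 (IL-22 KO). The design text describes separate mice, so the arrays of a group are biological replicates. Total RNA (5 µg per sample) was turned into biotin-labelled cRNA and hybridised to 1 Affymetrix array per mouse. Sex, litter, cage, time of collection and hybridisation date are not given in the sources used here.

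The deposited values are log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA and affy, with no version and no options. RMA usually corrects the background, normalises between arrays by quantiles and summarises the probes of a set. Which of these steps were run is not given in the sources used here. The log base was read from the range of the deposited values, 4.11 to 15.15, which fits log2 of a scanner signal. Scanner intensities, which another background correction would need, were not used here. No read depth applies to an array. The number of arrays and the brightness of a probe set limit the precision, and differences between values near either end of the scale are compressed.

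The file held 45101 probe sets with no missing value. Of these, 64 were control probe sets and stayed out of the tests. Among the rest, 34945 were listed with 1 gene, 932 with several genes and 9160 with none in the platform annotation used here. The Entrez identifiers of 34741 probe sets were found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols had to be updated. That table served only for names, synonyms and the order of neighbouring genes, since no genome build is named for the arrays. Each gene was represented by its brightest probe set over all 10 arrays, among those listed with that gene alone, which gave 18193 genes. Of these, 9010 had several probe sets. Il22 was measured only by a probe set shared with its near-identical copy Iltifb and so stood outside the gene count.

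IL-22 KO was compared with WT by limma 3.58.1 in R 4.3.3, with lmFit and eBayes, no covariate, no block and no filter on dim genes. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 18193 genes, and a gene was called at an adjusted p under 0.05. Intervals are 95% intervals from the same model. Single values of 5 against 5 arrays were also compared by an exact permutation test over the 252 assignments of the arrays, which cannot give a p below 0.00794. Differences are IL-22 KO minus WT on the log2 scale throughout.

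Before the data were examined, 43 gene lists were fixed for the response to IL-22, to interferon-γ and to infection, for the cell types of the gut wall and for metabolism, with check lists for neighbours of Il22, sex-linked genes and genes that differ between C57BL/6 substrains. A list was tested with camera of limma, which compares its genes with all others, at a preset correlation of 0.01 between genes and with adjustment over the 43 lists. A list needed 5 measured genes. Camera with an estimated correlation and fry, a rotation test of whether a list moves one way, were run as alternatives. Members of a list were also adjusted over the list alone. The genes named in the text follow a rule fixed at the same time. It takes Il22 and Il18, the 12 largest rises and the 12 largest falls among called genes, and in each list up to 4 members with the smallest p and every called member. Genes with probe sets that were called in opposite directions were to be marked as uncertain, and among the called genes there was none. A list score per array is the mean over the list of each gene's value minus its mean over the 10 arrays.

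The alternatives fixed in advance were the replicate number as a block, centring each array on its median, repeating the quantile normalisation, cyclic loess, filters at the median and at the 25th percentile of level, the mean of a gene's probe sets, leaving out the probe sets named _s_at and _x_at (which can match several transcripts), each probe set on its own, a variance trend with robust moderation, array weights, an unmoderated test with unequal variances, an adjusted p under 0.1, and leaving out each array in turn. Added after the data were seen were the exclusion of the IL-22 KO arrays 3 and 5, a smooth muscle score, a clock score and a split of the arrays described with the results, the last 3 as covariates. The clock score is the mean of 10 genes that peak towards evening minus the mean of 5 that peak towards morning. The replicate numbers of the groups did not pair the arrays.

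The test was first run on simulated data for this comparison, with 18193 genes at the observed levels and spreads and 200 genes changed. At this size it called 74% of 50 genes changed by 0.5 on the log2 scale, 98% of those changed by 1, and 100% of those changed by 2 or 3. Of all calls, 5.58% were false. With no change simulated, camera passed 0 of 43 lists, but the simulated genes were independent of one another, unlike measured genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.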

Results

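Gene expression in the ileum was compared between 5 WT and 5 IL-22 KO mice, 5 days after oral infection with Toxoplasma gondii, a protozoan parasite that invades the small intestinal wall. Interleukin-22 is a cytokine of lymphoid cells that acts on epithelium. The series asks which ileal genes depend on it during this infection. Uninfected mice were not analysed here, so each difference is one between infected animals. Arrays correlated at 0.985 to 0.996 within WT, at 0.984 to 0.995 within IL-22 KO and at 0.978 to 0.993 between the groups, and no 2 arrays of a group held identical values. The first principal component held 36.4% of the variance and differed between the groups (exact permutation test, two-sided p = 0.00794, the smallest that 5 against 5 arrays allow; 0.0476 after adjustment over 6 array measures).

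The probe set for Il22, which it shares with the copy Iltifb and which names neither alone, read 5.44 ± 0.19 in WT and 5.02 ± 0.11 in IL-22 KO (SD, n = 5 each). All 5 IL-22 KO arrays lay below all 5 WT arrays (difference -0.41, SE 0.095; exact permutation test, two-sided p = 0.00794). Its individual values were 5.27, 5.55, 5.67, 5.48 and 5.21 in WT and 5.19, 4.95, 5.04, 5.04 and 4.90 in IL-22 KO. The WT mean stood at the 3.89th percentile of gene levels. Y-linked genes read 4.69 to 7.49 in the same arrays, and Xist 11.39 to 12.62, so such levels lie near the background. Whether the probes lie in the deleted part of the gene is not given in the sources used here, so this low signal is a weak check of the labels.

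A small group of genes lost most of its expression in IL-22 KO ileum. Plet1, which encodes an epithelial surface protein, had the largest fall, from 13.48 ± 0.19 to 9.22 ± 0.44 (SD, n = 5), which is 19.2-fold (difference -4.26, SE 0.18, limma adjusted p = 3.06e-07). The serum amyloid A genes Saa1 and Saa2, acute-phase proteins also made in gut epithelium, were 6.42-fold and 4.92-fold lower. Saa2 was measured by 1 _x_at probe set only, a kind that can match several transcripts, so its fall may not be its own. Il18, a cytokine of the IL-1 family made by epithelial cells, went from 11.004 ± 0.41 to 8.56 ± 0.41 (SD, n = 5), which is 5.44-fold lower. Its difference was -2.44 (95% interval -2.92 to -1.97, limma adjusted p = 1.69e-04), and only 2 of the 252 assignments of arrays gave one as large (exact permutation p = 0.00794). The remaining 8 of the 12 largest falls were those of Pla2g5, a secreted phospholipase (-2.18), B3gnt7, a glycosyltransferase (-2.12), Slc9a3, an apical sodium-proton exchanger (-1.83), Tac1, the precursor of substance P (-1.80), Chst4, a sulfotransferase (-1.76), Bhmt (-1.67) and Tat (-1.66), enzymes of methionine and tyrosine metabolism, and Fut2, a fucosyltransferase (-1.61). Each of the 12 had groups that did not overlap, with adjusted p at or below 0.00914 (limma).

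Among the genes that rose, Ctse, which encodes the aspartic protease cathepsin E, had the largest rise, 2.14 (SE 0.18, limma adjusted p = 1.36e-04), from 9.90 ± 0.40 to 12.04 ± 0.27 (SD, n = 5). This rested on 1 _s_at probe set: without that kind of probe set the value for Ctse was -0.073 (adjusted p = 0.698). Cubn, the intestinal receptor for vitamin B12 bound to intrinsic factor, rose by 2.00, the cytochrome P450 gene Cyp2c55 by 1.98, Olfm4, a marker of crypt stem cells, by 1.97 and the phospholipase gene Pla2g4c by 1.86. The other 7 were Tmem267 (1.62), Nr1d2 (1.46), Gm6958 (1.45), Reg4 (1.36), Slc6a20a (1.35), the tRNA methyltransferase gene Trdmt1 (1.32) and Cyp4v3 (1.30). The adjusted p of the 12 rises went up to 0.0486, that of Cubn (limma). WT and IL-22 KO arrays overlapped for Cubn and Cyp4v3. Fitted with a covariate for the array split described last, 8 of the 12 rises were no longer called, all but Ctse, Olfm4, Tmem267 and Reg4, and 1 of the 12 falls, Chst4. These 9, chosen by their difference in the same arrays, kept their sign and an unadjusted p under 0.05. Chst4 went from -1.76 to -1.91 (SE 0.38), Cyp2c55 from 1.98 to 1.75 (SE 0.35), Cubn from 2.00 to 1.71 (SE 0.65) and Trdmt1 from 1.32 to 1.14 (SE 0.24); the standard errors were wider with the covariate. Leaving out any single array but IL-22 KO 1 ended the call of at least 1 of Cubn, Cyp4v3, Pla2g4c, Nr1d2 and Reg4, and of no other gene of the 24.

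**Figure D1:**
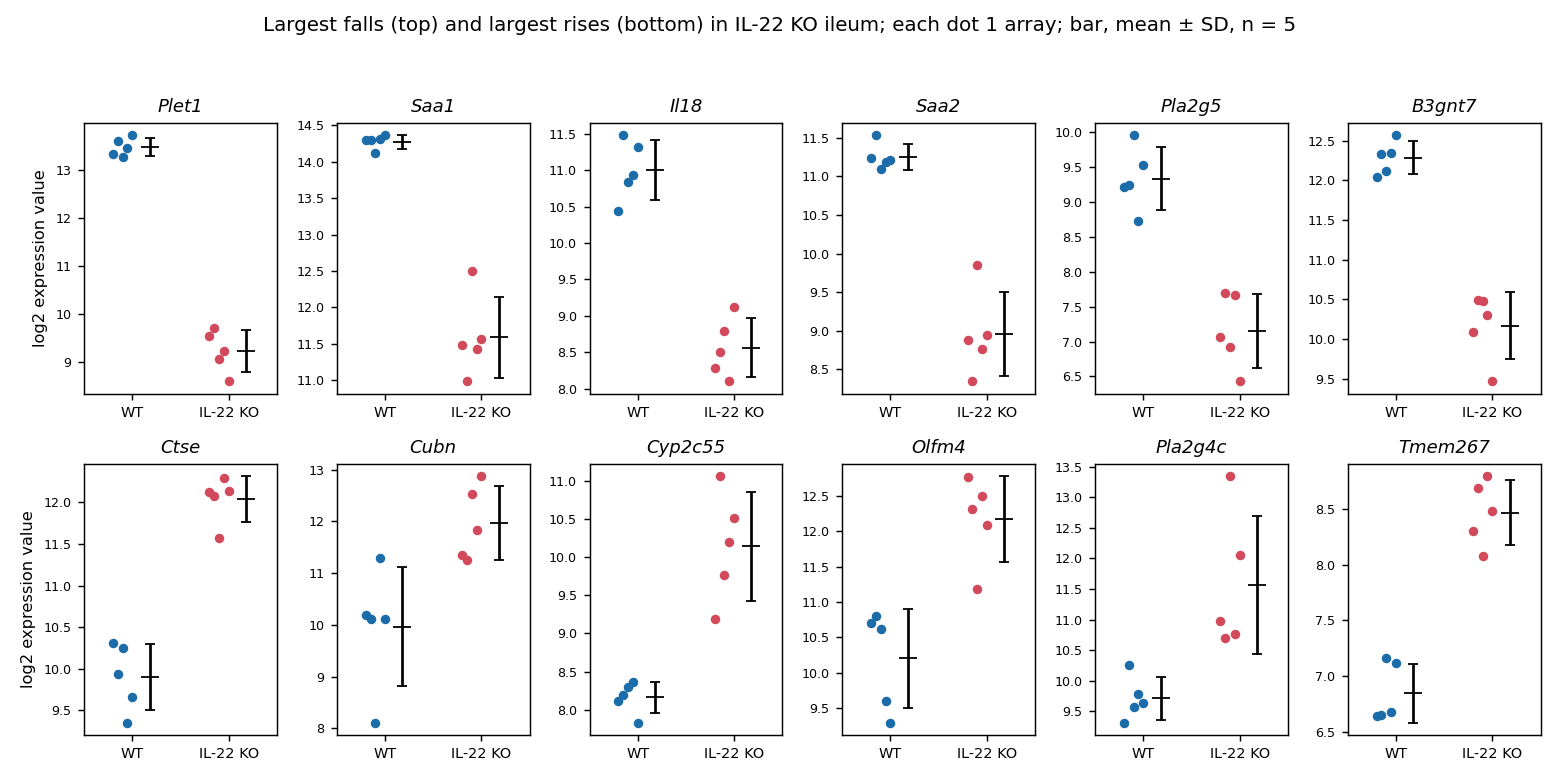
Log2 expression values (vertical axes, 1 scale per gene) of the 6 largest falls and the 6 largest rises in WT and IL-22 KO ileum; each dot is 1 array and the black bars are mean ± SD, n = 5. The groups are apart for every gene shown but Cubn, and Plet1 drops from 13.48 to 9.22.

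In all, 630 of 18193 genes passed an adjusted p of 0.05, 367 higher and 263 lower in IL-22 KO, and 5259 had an unadjusted p under 0.05 (limma). Only 28 of the higher and 26 of the lower genes changed at least 2-fold. The median change was 0.46 among the higher and -0.40 among the lower genes. Groups did not overlap for 1168 genes, 6.42% of all, against 0.794% expected by chance for a single gene. Genes vary together between arrays, and the array split described last shares most of its arrays with the genotypes. The excess is therefore not read as genotype alone. The share of higher genes among those called depended on scaling. It was 58.3% on the deposited values, 48.0% after cyclic loess and 34.3% when the quantile normalisation was repeated. The direction of the calls also went with expression level. In the third decile of level 18 genes were called higher and 36 lower, in the ninth 68 and 20, and in the tenth 45 and 44. The array split described last has a like form in the third and ninth deciles, so these directions are not read as genotype alone.

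The size of this count depended on single arrays. It rose to 4207 without IL-22 KO 1 and fell to 230 without WT 1, 183 without WT 2, 303 without WT 4, 259 without WT 5, 267 without IL-22 KO 2, 404 without IL-22 KO 3, 254 without IL-22 KO 4 and 265 without IL-22 KO 5. An unmoderated test per gene called 61 genes (4409 at an unadjusted p under 0.05).

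A part of the genes known to respond to IL-22 fell. Of 33 measured members, 11 fell, 1 rose and 21 did not pass; adjusted over the list alone, 17 fell and 1 rose. The C-type lectins Reg3g and Reg3b, antimicrobial proteins of the epithelium, were among the brightest genes on the arrays. Reg3g fell by 1.32 (SE 0.07, limma adjusted p = 1.03e-06) from 14.87 ± 0.05, and Reg3b fell by 0.74 from 15.07 ± 0.07 (SD, n = 5), close to the highest value in the file, 15.15. Saa1, Saa2, Pla2g5 and Fut2 are members described above. Tifa, an adaptor of innate signalling, fell by 1.55, Duoxa2, the maturation factor of the oxidase DUOX2, by 0.97, Socs3, a feedback inhibitor of cytokine receptors, by 0.94, the nitric oxide synthase gene Nos2 by 0.70 and the transglutaminase gene Tgm2 by 0.61. Socs3 and Tgm2 each lost their call when any 1 of 8 arrays was left out. The member that rose was Reg4, a relative of the Reg3 genes (1.36). The list had a mean of -0.45 and passed camera (adjusted p = 5.25e-05). That call was lost with an estimated correlation (adjusted p = 0.781).

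Genes of mucins and of the enzymes that add sugars to them were lower. Of 29 measured, 5 fell, none rose and 24 did not pass; over the list alone 9 fell. B3gnt7 fell by 2.12, Fut2 by 1.61, B3galt5 by 0.73, B4galt1, a galactosyltransferase, by 0.50 and Muc13, a transmembrane mucin, by 0.46. List scores were 0.073 to 0.28 in WT and -0.27 to -0.094 in IL-22 KO, with no overlap. The mean was -0.33 (camera adjusted p = 6.74e-05; 0.209 with an estimated correlation). Goblet cell markers as a list did not pass (mean -0.052, adjusted p = 0.939), and their mean was below 0 while their median was above it. Without IL-22 KO 3 and 5, an exclusion chosen after the data were seen, goblet markers stood at 0.19 (adjusted p = 6.59e-04).

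Genes induced by interferon-γ, the main cytokine of defence against this parasite, were slightly higher in IL-22 KO. Of 34 measured, 4 rose and 30 did not pass; over the list alone 10 rose. They were Ciita, the regulator of MHC class II genes (0.54, SE 0.08, limma adjusted p = 0.00429), Irf8 (0.41), the MHC class I regulator Nlrc5 (0.43) and Irf1 (0.24). Nlrc5 and Irf1 each lost their call when any 1 of 9 arrays, all but IL-22 KO 1, was left out, and Irf8 lost its call with the array split as a covariate. The mean was 0.29, and the score of 4 of 5 IL-22 KO arrays lay above every WT array. Camera gave an adjusted p of 2.80e-08, and 0.781 with an estimated correlation. Ifng read 6.80 ± 0.49 in WT and 7.54 ± 0.67 in IL-22 KO (SD, n = 5; limma adjusted p = 0.14). The list of type I interferon response genes did not pass (mean -0.024, adjusted p = 0.704).

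Beside Il18, the list of inflammasome and IL-18 genes held 2 genes that rose, Gsdmc2, a gasdermin (1.23, SE 0.19, limma adjusted p = 0.00705), and Nlrp6, an epithelial NOD-like receptor (0.40), whose call ended when any 1 of 8 arrays was left out. Both Gsdmc2 and Nlrp6 lost their calls with the clock score and with the array split as covariates. The other 17 of 20 did not pass, among them Casp4 (-0.38, adjusted p = 0.0864). The list as a whole did not pass (camera adjusted p = 0.846). Its mean was -0.036, its median 0.053 and the direction of the test upward, so that the 3 differ in sign.

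Markers of crypt stem cells had a higher mean, but did not all move one way. Of 19 measured, 7 rose, 1 fell and 11 did not pass. Adjusted over the list alone, 9 rose and 4 fell. Olfm4 (1.97), Cd44 (0.73), Smoc2 (0.69), Cdca7 (0.58), Slc12a2 (0.55), Lgr5, the receptor that marks these cells (0.45), and Rnf43 (0.43) rose, and the water channel gene Aqp4 fell by 1.45. The mean was 0.21 (camera adjusted p = 0.0158; 0.781 with an estimated correlation; 0.0551 without IL-22 KO 1). It was also lost among genes above the median level (adjusted p = 0.378) and above the 25th percentile (0.0968). Cd44, Slc12a2 and Cdca7 lost their calls when any 1 of 8, 7 and 7 arrays was left out. Lgr5 lost its call when any 1 of 5 arrays was left out, with the replicate block and with the mean of its probe sets. Rnf43 lost its call without any 1 of 3 arrays, and Aqp4 with the replicate block. With the array split as a covariate, Cd44, Smoc2, Cdca7, Slc12a2, Rnf43 and Aqp4 lost their calls, while Olfm4 and Lgr5 kept theirs. With the clock score, Cd44, Slc12a2, Lgr5, Rnf43 and Aqp4 lost theirs. In the proliferation list, 2 of 29 genes rose, the replication genes Mcm5 (0.53) and Mcm2 (0.44), and 27 did not pass (mean 0.18, camera adjusted p = 0.0107; 0.829 with an estimated correlation). Leaving out WT 4, IL-22 KO 1, IL-22 KO 2 or IL-22 KO 4 ended that call (adjusted p = 0.0739, 0.0592, 0.092 and 0.0685), with a mean of 0.11 without WT 4 and 0.095 without IL-22 KO 2, and so did the filters at the median and at the 25th percentile of level (0.378 and 0.0899). The proliferation mean was larger in fits chosen after the data were seen, 0.43 without IL-22 KO 3 and 5 and 0.62 with the clock score as a covariate. Mcm5 and Mcm2 each lost their call without any 1 of 6 arrays. Ribosomal protein genes had a mean of 0.12 with none of 19 past the threshold (camera adjusted p = 0.00991; 0.804 with an estimated correlation). This is about the median difference of all genes in the seventh to ninth deciles of level, 0.10 to 0.11, and above the 0.053 of the tenth. Which deciles hold the ribosomal genes was not analysed here. The filters at the median and at the 25th percentile ended the call of this list (camera adjusted p = 0.354 and 0.0838). The ribosomal mean was 0.22 without IL-22 KO 3 and 5 and 0.29 with the clock score.

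Clock genes differed between the groups. Per2 (1.17), Nr1d2 (1.46) and Nr1d1 (1.01), the last 2 encoding the REV-ERB repressors, rose, Cry1 fell by 0.53, and 13 of 17 did not pass. The mean was 0.41 (camera adjusted p = 0.0349; 0.781 with an estimated correlation), and the call was lost without WT 3 or IL-22 KO 5 (adjusted p = 0.0658 and 0.0568), with the array split as a covariate (0.0768) and under the filters at the median and at the 25th percentile of level (0.448 and 0.174). Nr1d1 lost its call in 17 of 25 alternatives and Cry1 in 16 of 24. In the list of detoxification and redox genes, Cyp2c55 (1.98), Ugt2b5 (1.23), Cyp2c65 (0.97) and Gclm (0.41) rose, the glutathione peroxidase gene Gpx2 fell by 0.57, and 24 of 29 did not pass (mean 0.28, camera adjusted p = 0.0474; 0.781 with an estimated correlation). That call was lost after cyclic loess (adjusted p = 0.0699) and without WT 3, IL-22 KO 1, IL-22 KO 3 or IL-22 KO 5 (adjusted p = 0.208, 0.0592, 0.0798 and 0.177). It was also lost with array medians centred (0.0649), without _s_at and _x_at probe sets (0.05004), with array weights (0.193) and under the filters at the median and at the 25th percentile of level (0.876 and 0.236). Among the fits chosen after the data were seen, the detoxification mean was 0.19 with the array split (0.111), 0.24 with the muscle score (0.226), 0.18 without IL-22 KO 3 and 5 (0.461) and 0.10 with the clock score (0.963). Cyp2c65 lost its call in 18 of 23 alternatives, Ugt2b5 in 10 of 24, Gclm in 9 of 25 and Cyp2c55 in 1 of 25.

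Lists of smooth muscle, stroma and matrix genes had higher means in IL-22 KO, and the muscle and stroma scores were highest in 2 of its arrays. The smooth muscle score was 1.23 in IL-22 KO 3 and 0.77 in IL-22 KO 5, against -0.62 to -0.084 in the other IL-22 KO arrays and -0.36 to 0.096 in WT. None of the 19 smooth muscle genes passed, with Hspb7 at 0.57, Csrp1 at 0.58, Des at 0.58 and Cnn1 at 0.68. That list's mean was 0.38 (camera adjusted p = 0.0143; 0.804 with an estimated correlation), and -0.16 without IL-22 KO 3 and 5. Leaving out IL-22 KO 3 alone or IL-22 KO 5 alone ended that call (adjusted p = 0.253 and 0.162). The stroma and endothelium list had a mean of 0.28 with none of 20 past the threshold (camera adjusted p = 0.0039; 0.804 with an estimated correlation) and of 0.075 without those arrays (adjusted p = 0.461), and leaving out IL-22 KO 5 alone ended its call (adjusted p = 0.0568). In the matrix list, Mmp2 rose by 0.40 and 23 of 24 did not pass, and that call of Mmp2 ended when any 1 of 8 arrays was left out (mean 0.31, camera adjusted p = 0.00557; 0.781 with an estimated correlation). Cholesterol synthesis genes had a mean of 0.17, with the sterol carrier gene Stard4 higher by 0.38 (camera adjusted p = 0.00557; 0.804 with an estimated correlation; 0.0545 after cyclic loess and 0.0599 without IL-22 KO 5). That mean was 0.037 with the array split as a covariate (adjusted p = 0.265), 0.011 with the clock score (0.839) and 0.085 without IL-22 KO 3 and 5 (0.189), and Stard4 lost its call in these 3 fits. Chemokines and cytokines had a mean of 0.20 with none of 32 past the threshold (camera adjusted p = 0.0373; 0.781 with an estimated correlation), a call that ended without WT 4, WT 5, IL-22 KO 1 or IL-22 KO 2 (adjusted p = 0.0618, 0.0721, 0.152 and 0.092). Pancreatic enzyme genes, a check for attached pancreas, had a mean of -0.15, and Cel fell by 0.40 (camera adjusted p = 0.0204; 0.781 with an estimated correlation). It was -0.089 with the array split (adjusted p = 0.117), and the call also ended above the 25th percentile (0.0899), without IL-22 KO 3 and 5 (0.0551) and with the clock score (0.0682).

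**Figure D2:**
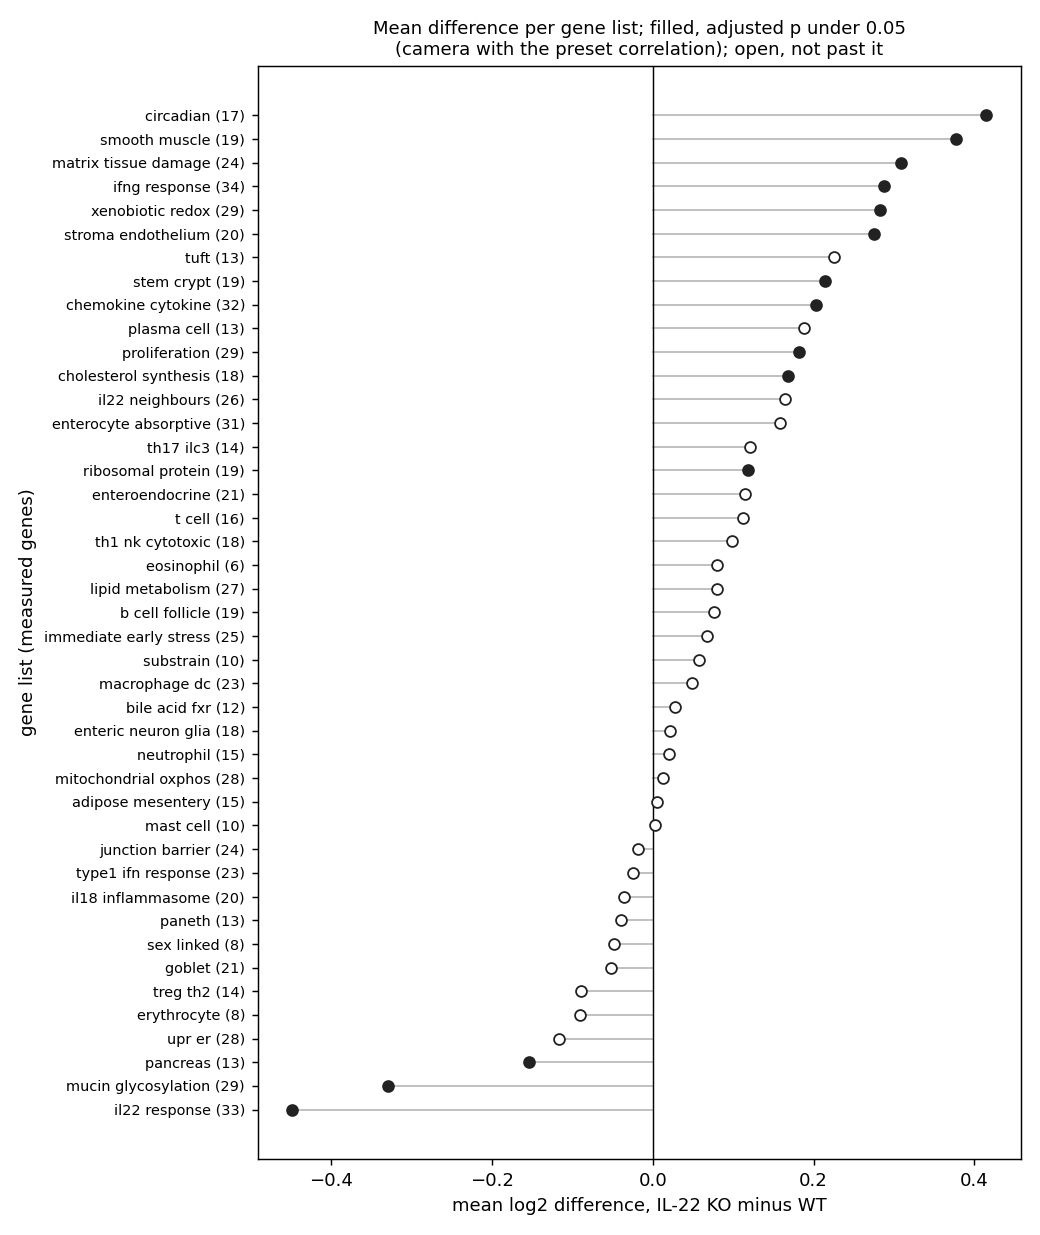
Mean log2 difference, IL-22 KO minus WT (horizontal axis), of each of the 43 gene lists (vertical axis, with the number of measured genes); filled dots passed camera with the preset correlation. The lowest means are those of the IL-22 response (-0.45) and of mucins and glycosylation (-0.33), and the highest that of the clock genes (0.41).

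Of the 43 lists, 14 passed camera with the preset correlation, 11 upward and 3 downward. None passed with an estimated correlation (camera of limma; the smallest unadjusted p was 0.00485, that of mucins and glycosylation). Fry passed 3, mucins and glycosylation (adjusted p = 0.00255), the IL-22 response (0.0157) and the interferon-γ response (0.0438). For camera with the preset correlation, 52 of 100 splits of the arrays gave at least 14 lists, with 24 as the highest other. Chance can therefore not be excluded for the number of lists. A pass with the preset correlation alone is not read as an effect of genotype. Which lists passed in the other splits was not analysed here. Lists of T cells (camera adjusted p = 0.265), B cells and follicles (0.735), macrophages and dendritic cells (0.802), neutrophils (0.335), Paneth cells (0.723), tuft cells (0.169) and absorptive enterocytes (0.306) did not pass.

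**Figure D3:**
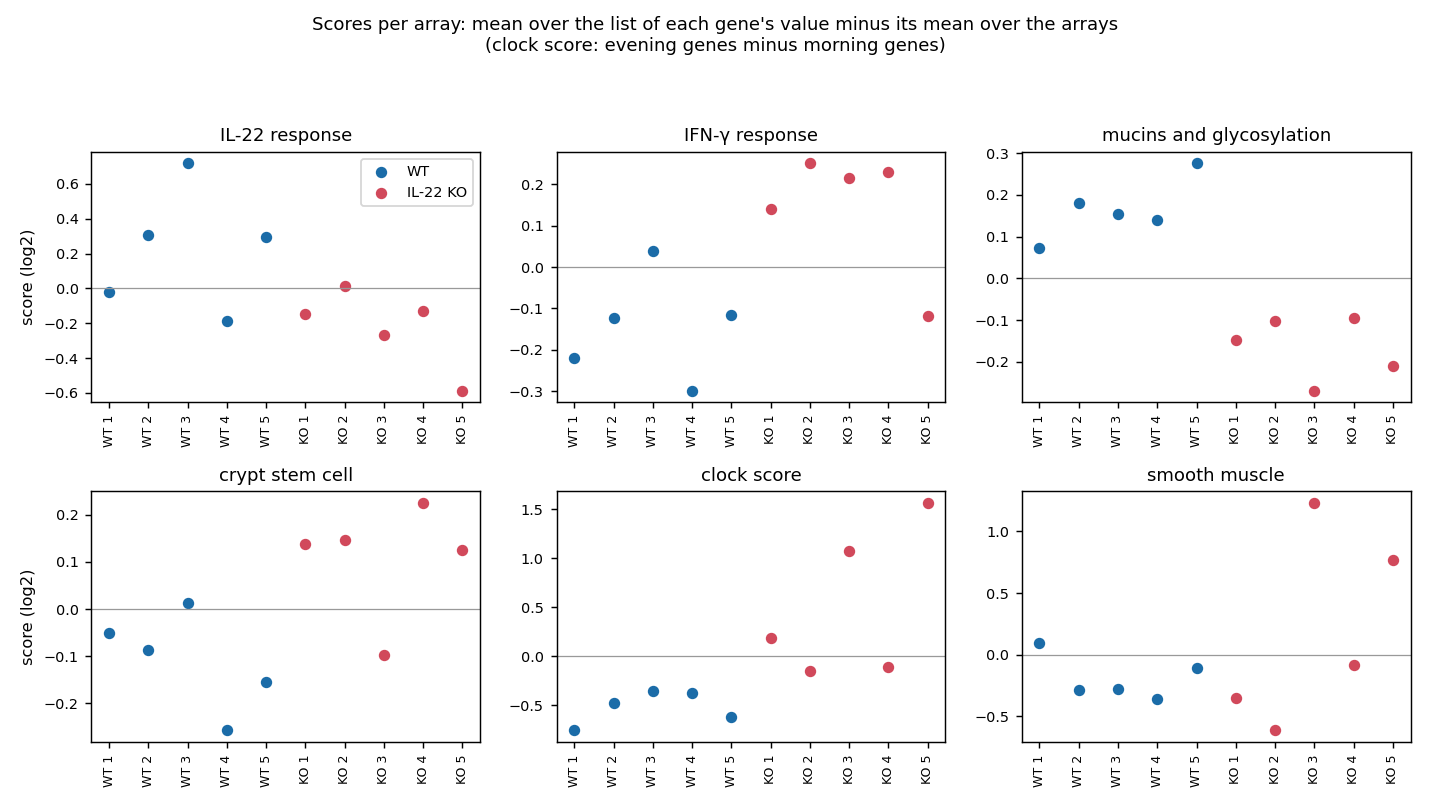
Score per array (vertical axes, log2; the mean over a list of each gene's value minus its mean over the 10 arrays) for 6 sets of genes, with the arrays along the horizontal axes; the clock score is evening genes minus morning genes. Mucin and glycosylation scores separate the groups, while the smooth muscle score is high only in IL-22 KO 3 (1.23) and IL-22 KO 5 (0.77).

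The arrays also split in a way that did not follow genotype alone. When WT 5 and IL-22 KO 1 changed places, so that WT 1 to 4 and IL-22 KO 1 stood against WT 5 and IL-22 KO 2 to 5, 1729 genes passed, more than the 630 of the real groups. The swapped sets share 4 of 5 arrays with the genotypes, so genotype differences enter that count. With genotype in the model, the split called 0 genes (limma; 3020 at an unadjusted p under 0.05). The medians of the arrays of the first set were 7.94 to 7.97 and those of the second 7.89 to 7.93, and 18S ribosomal RNA control probe sets read 6.88 to 7.38 and 6.34 to 6.79. That control also read lower in IL-22 KO, 6.59 ± 0.23 against 7.15 ± 0.30 in WT (SD, n = 5). The exact permutation test gave a two-sided p of 0.0238, and 0.0714 after adjustment over 6 array measures, which is not under 0.05. In the second set, genes of the third decile of level were lower by a median difference of -0.15 and those of the ninth were higher by 0.17. The genotypes showed the same form, -0.13 and 0.11. With the split as a covariate, 134 genes passed for genotype, 33 higher and 101 lower, of which 115 were among the 630. All 630 kept their sign and an unadjusted p under 0.05 in that fit. They had been chosen by their genotype difference in the same arrays, so this is no separate test. After cyclic loess, the swapped sets differed in 0 genes (limma) and the genotypes in 600, of which 429 were among the 630. Within a set, genotype cannot be told from the single animal of the lone array (4 WT arrays and 1 IL-22 KO array in the first, 1 and 4 in the second). Such fits passed 6 and 2 genes (limma; 734 and 1464 at an unadjusted p under 0.05), which are not read as genotype calls.

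**Figure D4:**
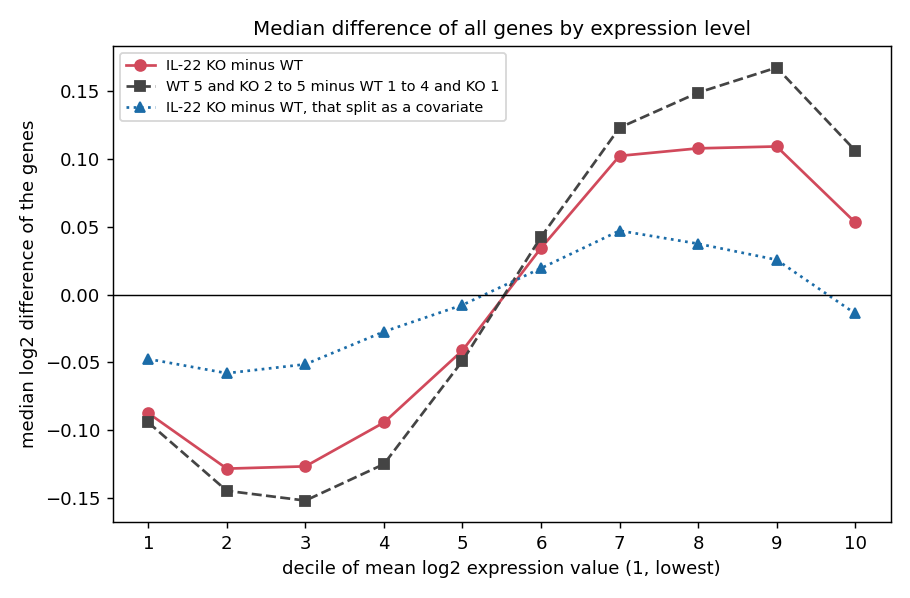
Median log2 difference of all genes (vertical axis) by decile of mean expression level (horizontal axis, 1 is the lowest). Red circles are IL-22 KO minus WT, grey squares the swapped sets of arrays, and blue triangles IL-22 KO minus WT with those sets as a covariate; red and grey run from -0.13 and -0.15 in the third decile to 0.11 and 0.17 in the ninth.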

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

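The tests of a wrong label, of mixed RNA and of a level-dependent shift in IL-22 KO 1 were chosen only after the results were seen.

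In 7 of 138 groups of 5 values, 1 array stood apart from the others of its group by Dixon's criterion, where chance gives about 6.9. Saa1 in WT 3 read 14.12, below the 14.29 to 14.36 of the other WT arrays. Ctse, whose rise rested on 1 _s_at probe set, read 11.57 in IL-22 KO 3, against 12.08 to 12.29 in the other IL-22 KO arrays. List scores stood apart for pancreatic enzymes in IL-22 KO 1 (0.071), lipid metabolism in IL-22 KO 1 (-0.21), adipose and mesentery in IL-22 KO 1 (-0.64), Paneth cells in IL-22 KO 4 (0.12) and macrophages and dendritic cells in WT 3 (0.20). The number is what chance gives, so no single one of these is read further.

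Probe sets with no gene listed were outside the gene counts. Of 9160 such probe sets, 75 passed the threshold, 27 higher and 48 lower in IL-22 KO (limma, adjusted among all probe sets but controls). The largest rises among them were 2.84, from 10.61 ± 0.85 to 13.46 ± 0.18 (SD, n = 5), and 1.86, and the largest falls were -1.53 and -1.23. Which transcripts they measure was not analysed here.

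IL-22 KO 1 was the array whose removal changed the gene count most, to 4207. A wrong label was tested on genes chosen without this array. Of the 12 largest falls called among the other 9 arrays, 12 lay below every WT array in IL-22 KO 1, and of the 12 largest rises 11 lay above. For WT arrays left out in the same way, 0 to 5 of the falls lay below every other WT array and 2 to 8 of the rises above, so the rises part the arrays less. For the other IL-22 KO arrays it was 12 of the falls and 10 to 12 of the rises. The falls argue against a WT animal under this label. Mixed RNA was tested by placing the array between the group means. The 12 largest falls implied a WT share of -3.18%, and 4195 other genes called without the array implied 85.2% (95% interval 83.9 to 86.6). A mixture needs 1 share for all genes, so these values argue against it. For the other IL-22 KO arrays, the other-gene share was -3.35% to 16.9%. It came from only 242 to 392 genes, which were called with IL-22 KO 1 in the group. The sets of genes differ, so these shares are not a like comparison with that of IL-22 KO 1.

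A shift that depends on signal level and parts the arrays as WT 1 to 4 with IL-22 KO 1 against WT 5 with IL-22 KO 2 to 5 remains open. That split, which shares 4 of 5 arrays with the genotypes, called 0 genes with genotype in the model (limma; 3020 at an unadjusted p under 0.05). Alone it called 1729 genes on the deposited values, 378 after a repeated quantile normalisation and 0 after cyclic loess, a scaling that removes level-dependent differences, whereas the genotypes called 600 after it. Such a shift may explain the place of IL-22 KO 1. It could come from labelling or hybridisation or from the tissue pieces, and no collection or hybridisation date was used here that would tell these apart. No biological explanation was tested for it. With the split as a covariate, 134 genes were called for genotype.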

How the results depend on the processing

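The exclusion of IL-22 KO 3 and 5 and the fits with the muscle score, the clock score and the array split as covariates were chosen only after the data were seen.

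Il18 was lower in IL-22 KO and past the threshold under every alternative recorded gene by gene, with -2.32 to -2.95 as its range. The unmoderated test and the test of each probe set on its own were counted only in total. The shared Il22 probe set stayed lower wherever it had a value; leaving out single arrays gave -0.47 to -0.35, and the array split as a covariate gave -0.26. It had no value under the filters on level and without _s_at probe sets. Of the 12 named falls and 12 named rises, 24 were called with array weights, 21 after cyclic loess and 15 with the array split or with the clock score as a covariate.

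The number of genes changed depended on the processing. Against 630 (367 higher, 263 lower), it was 212 (130 and 82) with the replicate number as a block, although the numbers do not pair the arrays, and 199 of these were among the 630. Array weights gave 3788 (1669 and 2119). An unmoderated test per gene gave 61 (30 and 31), and an adjusted p under 0.1 gave 2203. A repeated quantile normalisation gave 662, with 227 higher and 435 lower, and cyclic loess 600. Genes above the median level numbered 382, with 116 lower, as fewer genes were tested. Without IL-22 KO 3 and 5 there were 415, with 103 lower; here fewer arrays were compared. The clock score as a covariate gave 182 (140 and 42) and the array split 134 (33 and 101). The cause was not tested for the block, the weights and the covariates.

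Against 14 gene lists past the threshold, 6 passed among genes above the median level and 7 above the 25th percentile, not all of them among the 14, as well as 0 in camera with an estimated correlation and 3 in fry. With an estimated correlation, the IL-22 response (-0.45) and the interferon-γ response (0.29) kept their means and lost their calls (adjusted p = 0.781 for both), as the genes of a list vary together between mice. Their adjusted p ranged from 3.19e-07 to 0.00208 and from 1.66e-12 to 6.11e-06 when single arrays were left out.

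Several results changed sign under some settings, among them Ctse (2.14) and the lists of smooth muscle (0.38) and of stroma and endothelium (0.28). With array medians centred, the sign changed for the list of junctions (0.0049). With the quantile normalisation repeated, the sign changed for the lists of macrophages and dendritic cells (-0.0021), bile acids (-0.010), adipose and mesentery (-0.026), immediate early genes (-0.0036) and oxidative phosphorylation (-0.032). After cyclic loess, the sign changed for the lists of oxidative phosphorylation (-0.042) and sex-linked genes (0.0073). Among genes above the median level, the sign changed for the lists of goblet cells (0.0056) and bile acids (-0.13). Above the 25th percentile, the sign changed for the lists of neutrophils (-0.030), bile acids (-0.052) and adipose and mesentery (-0.0078). With the mean of probe sets, the sign changed for the genes Ebf1 (0.0061) and Rps4x (-0.084) and for the list of adipose and mesentery (-0.012). Without _s_at and _x_at probe sets, the sign changed for the genes Ctse (-0.073) and Lss (-0.091) and for the lists of neutrophils (-0.045) and bile acids (-0.085). With array weights, the sign changed for the lists of mast cells (-0.041), goblet cells (0.015) and junctions (0.023).

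Without IL-22 KO 3 and 5, the sign changed for the genes Ccl6 (0.16), Cnn1 (-0.077) and Spink4 (0.011) and for the lists of type I interferon response (0.027), Th1 and cytotoxic cells (-0.014), macrophages and dendritic cells (-0.025), mast cells (-0.070), goblet cells (0.19), absorptive enterocytes (-0.074), bile acids (-0.079), junctions (0.041), smooth muscle (-0.16), enteric neurons and glia (-0.063) and adipose and mesentery (-0.095). With the muscle score, the sign changed for the lists of mast cells (-0.055), goblet cells (0.11), bile acids (-0.024), junctions (0.023), enteric neurons and glia (-0.049) and adipose and mesentery (-0.037). With the clock score, the sign changed for the genes Ccl6 (0.47), Cd3g (-0.10), Cnn1 (-0.42), Cyfip2 (-0.0013), Des (-0.035), Dsc2 (0.10), Gzmk (-0.038), Itgax (-0.086), Lat (-0.026), Lrrn4 (-0.045), Slc2a5 (-0.11), Snap25 (-0.10), Spink4 (0.082) and Uqcrc2 (0.022) and for the lists of type I interferon response (0.11), Th1 and cytotoxic cells (-0.11), T cells (-0.067), plasma cells (-0.015), macrophages and dendritic cells (-0.082), mast cells (-0.13), goblet cells (0.32), absorptive enterocytes (-0.27), bile acids (-0.15), ER stress (0.027), junctions (0.081), smooth muscle (-0.44), stroma and endothelium (-0.087), enteric neurons and glia (-0.084) and adipose and mesentery (-0.11). With the array split, the sign changed for Ndufb3 (-0.042) and for the lists of lipid metabolism (-0.026), bile acids (-0.12), enteric neurons and glia (-0.0040), adipose and mesentery (-0.11) and oxidative phosphorylation (-0.039). Of these, goblet cells passed the threshold without IL-22 KO 3 and 5, with the muscle score and with the clock score, and absorptive enterocytes and smooth muscle did so with the clock score. Except for the probe sets left out or averaged in the cases of Ctse, Lss, Ebf1 and Rps4x, the cause was not tested.

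Leaving out each array in turn gave 183 (without WT 2) to 4207 genes (without IL-22 KO 1), 105 to 1599 higher and 78 to 2608 lower, and 9 to 19 lists. Lists with a mean near 0 changed sign within these ranges: bile acids (-0.036 to 0.099), oxidative phosphorylation (-0.012 to 0.037), Paneth cells (-0.13 to 0.023), type I interferon response (-0.077 to 0.066), adipose and mesentery (-0.080 to 0.17), neutrophils (-0.050 to 0.099), mast cells (-0.049 to 0.070), junctions (-0.046 to 0.015), enteric neurons and glia (-0.040 to 0.056), B cells and follicles (-0.029 to 0.14) and goblet cells (-0.13 to 0.093). The calls of the interferon-γ response, the IL-22 response, mucins and glycosylation, matrix, ribosomal proteins and pancreatic enzymes were kept without any single array, but those of ribosomal proteins and pancreatic enzymes ended under the filter at the 25th percentile of level (adjusted p = 0.0838 and 0.0899), and that of matrix with the clock score (0.295).

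Of 5845 compared values, 100 belonging to 38 results were past the threshold under neither setting and changed sign. The smooth muscle list with the muscle score and the clock list with the clock score were not compared, since each score is made from its list's genes. Another background correction needs scanner intensities and was not run. Signal near the background limits what dim probe sets, that of Il22 among them, can show, and Reg3b near the top of the scale can be understated.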

Other observations

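Of the tests given here, those of the difference between evening and morning genes, of its dependence on muscle and of the IL-22 response members with the clock score were chosen only after the results were seen.

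Several lists did not pass but held genes that did. In lipid metabolism (mean 0.079, camera adjusted p = 0.107), Ppara (0.47), Plin2 (0.44), Scd2 (0.43) and Fads2 (0.39) rose and Acadl fell by 0.89. Among tuft cell genes (mean 0.23, adjusted p = 0.169), Rgs13 (1.20) and Cd24a (0.75) rose. Among enteroendocrine genes (mean 0.11, adjusted p = 0.295), Chgb (1.14) and Reg4 (1.36) rose while Tac1 fell by 1.80. Abcc2 rose by 1.09, Spib by 0.56, Sdc1 by 0.42 and Ahr by 0.40. Pla2g2a fell by 0.83, the neutrophil granule gene Ltf by 0.70, Marveld3 by 0.44 and Ccr4 by 0.35. Of these genes, Ccr4 lost its call when any 1 of 9 arrays was left out, and Ahr, Sdc1, Spib and Marveld3 when any 1 of 8 was. Fads2 lost it without any 1 of 7 arrays, Reg4 of 5, Pla2g2a and Rgs13 of 4 and Abcc2 of 3. With the array split as a covariate, Ppara, Plin2, Scd2, Fads2, Rgs13, Cd24a, Chgb, Abcc2, Spib, Sdc1, Ahr, Pla2g2a and Ccr4 lost their calls. With the clock score the same genes but Chgb did, and so did Acadl, Ltf and Marveld3. The mean, the median and the test of a list differed in sign for neutrophils, mast cells, adipose and mesentery, enteric neurons and glia, inflammasome and IL-18, bile acids, goblet cells and eosinophils.

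The named falls held under more alternatives than the named rises. Of 31 called lower genes among those named and the list members, 16 were called under every alternative recorded gene by gene, leaving out single arrays included: B3gnt7, B4galt1, Bhmt, Duoxa2, Il18, Nos2, Pla2g5, Plet1, Reg3b, Reg3g, Saa1, Saa2, Slc9a3, Tac1, Tat and Tifa. Of 46 called higher genes, 3 were: Ciita, Olfm4 and Tmem267. Some of these genes lacked a value under a setting, as Saa2 did without _s_at and _x_at probe sets. The unmoderated test, which called 30 genes higher and 31 lower, was counted only in total. Whether it called these genes was not recorded. The exact permutation test among the alternatives used an unadjusted p.

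Other splits of the 10 arrays were counted, 100 of the 126 possible, with the real one among them. As many genes as the real 630 came from 2 splits, the highest other being 1729. A split has no direction of its own, so the larger direction of each split was set against the real count. Counts as large as that of genes higher in IL-22 KO (367) came from 2 splits, and as that of genes lower (263) also from 2. The highest other count was 1136 each time, the larger direction of a split with 593 and 1136 genes. Only 2 of 100 splits, the real one among them, reached each of these counts, so chance alone is an unlikely source of them. The other splits put both genotypes in each group, which widens the spread within groups, so they are no clean measure of chance. The 1729 genes came from exchanging WT 5 and IL-22 KO 1, a split that shares 4 of 5 arrays with the genotypes. The count points to a structure of the arrays, but not to its size: with genotype in the model that split called 0 genes (limma; 3020 at an unadjusted p under 0.05). For the number of gene lists, 52 of 100 splits gave at least the real 14, with 24 as the highest other, so chance cannot be excluded for it.

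Clock genes parted the groups. The mean of genes that peak towards evening minus that of genes that peak towards morning was higher in IL-22 KO by 1.03 (95% interval 0.22 to 1.84), and 5 of 5 IL-22 KO arrays lay above every WT array. It was largest in the arrays with the highest muscle scores, IL-22 KO 3 (1.08) and IL-22 KO 5 (1.57). The other IL-22 KO arrays read -0.15 to 0.19, and WT -0.76 to -0.36. Evening genes alone were higher by 0.73 (95% interval 0.24 to 1.21). For morning genes alone the difference was -0.30, with an interval that held 0 (-0.67 to 0.063). IL-22 KO 1 stood at 0.19, within the -0.15 to 1.57 of the other IL-22 KO arrays, which was also looked at. Collection of the groups at different times of day may explain this difference of 1.03, and times of collection were not analysed here. An effect of genotype on the clock stays open beside it. Muscle in the IL-22 KO pieces as the whole cause is argued against by the difference of 0.74 that was left with the smooth muscle score as a covariate (95% interval 0.15 to 1.34). With the clock score as a covariate, 12 of the 12 largest falls kept their sign and an unadjusted p under 0.05 (limma), among them Plet1 at -3.75 and Il18 at -2.95. So did 9 of the 12 largest rises. Of the 11 called lower members of the IL-22 response list, 9 did so. Socs3 (-0.94 to -0.43) and Tgm2 (-0.61 to -0.27) did not. All these genes had been chosen by their genotype difference in the same arrays, and the clock score itself parts the groups. The fit is therefore no separate test and does not decide whether the clock difference carries the falls. In that fit the mean of the whole IL-22 response list went from -0.45 to -0.21 (camera adjusted p = 0.00953). Fut2 (-1.61 to -1.52) and Chst4 (-1.76 to -1.34) lost their calls, and 42 genes were called lower instead of 263.

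Mice made from stem cells of another strain can keep that strain's DNA beside the targeted gene. Of the 50 measured genes nearest to Il22, 1 was called, Cpm (1.12), which is 2% against 3.47% of the others (odds ratio 0.569, 95% interval 0.014 to 3.33, Fisher's exact test, one-sided p = 0.829). Along the genome, the run of 25 neighbouring genes with the most calls held 7 (Rhov, Dll4, Ndufaf1, Itpka, Mga, Pla2g4e and Pla2g4d, named after their values were seen), where shuffled orders had a median of 5 (permutation p = 0.0719). With 1 call near Il22 and a run within the range of shuffled orders, these tests leave both questions open, and the strain of the stem cells is not given in the sources used here. Nnt, which differs between C57BL/6 substrains by a deletion, read 11.16 ± 0.08 in WT and 11.47 ± 0.08 in IL-22 KO (SD, n = 5). This rise was called, but the call ended in 13 of 25 alternatives, cyclic loess and the array split among them. The list of substrain genes did not pass (camera adjusted p = 0.306). Adjusted over that list alone, 1 of 10 measured genes rose and 2 fell.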
